A study of Nothobranchius furzeri with 10 samples.

How the data were processed

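RNA was sequenced from the brains of male turquoise killifish (Nothobranchius furzeri, a short-lived annual fish) aged 10 weeks, in 5 libraries labelled as having performed physical exercise in a swim tunnel and 5 libraries labelled as having no perturbation. All carried the same transgene, which by its name holds egfp and tfam under the mylz2 promoter. The fast skeletal muscle gene mylz2 encodes a myosin light chain, and tfam encodes a factor that takes part in the transcription of mitochondrial DNA and packages it. Libraries were made from total RNA with Illumina's TruSeq kit, version 2, per the labels' protocols, and that kit does not keep the strand, so reads of overlapping genes on opposite strands could not be told apart. The labels give no duration or intensity of swimming, no time between swimming and dissection, and no batch, litter or tank. They also do not say whether each library came from a separate fish, so the p-values measure the spread between these libraries.

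The authors deposited one table of raw counts per gene and one table named RPKM, each with 1 column per library and 26739 gene rows. The tools named in the submitters' processing notes are bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4. The genome build and the gene annotation are not given in the sources used here. Both tables hold gene identifiers of a single numbering scheme, and 0 of the 26739 identifiers occurred in the RefSeq gene table used for names. The files do not pair identifiers with gene names, and no row could be matched to the 32 pathway and cell type lists that had been fixed before the data were examined. Those lists, tfam and egfp were therefore not scored, and the set tests planned on the lists (camera and fry) were not run. The rule for named genes, fixed before the data were examined, took the largest changes among genes past the threshold with a mean of at least 1 CPM (counts scaled to a library of 1000000), at least 4 exercise libraries on the called side of the control median, and a gene symbol. The symbol condition could not be met by any row, and the rule was applied without it and limited to 2 genes that rose and 2 that fell.

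The RPKM values that the authors deposited were not used for the main comparison, because each value had been divided by the total of a library chosen by its place in the table. Counting cells down the columns, the 10 library totals had been applied in turn, over and over, so that 10.0% of cells received the total of their own library. With a whole-number gene length per row, this rule gave 99.997% of the 218026 values above 0 to within 0.0011, and the largest difference was 0.0016. With each library's own total, 1.94% were matched. The scaling error ranged from 0.556-fold to 1.80-fold, so values of one gene in this table cannot be compared between libraries as deposited. Gene lengths were recovered from the same equation for 22897 genes (median 2377 bp), the true totals being the column sums of the count table, and were used in the checks on gene length.

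Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, library sizes were scaled by the trimmed mean of M-values (TMM), and exercise was compared with control by the quasi-likelihood F test with robust estimation and no covariate. P-values were adjusted by the Benjamini-Hochberg method over 19325 genes with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F, and 95% intervals from them on 8 degrees of freedom. CPM values are TMM-scaled. For principal components, log2 CPM used a prior count of 2. Measures with one value per library were compared by two-sided exact permutation tests over the 252 assignments of 10 libraries to groups of 5, in which the smallest possible p is 0.00794, with adjustment over the 9 measures of the family. Intervals and tests cover these libraries and not PCR duplication, which was not marked by molecular identifiers.

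Alternatives fixed before the data were examined were 3 other scalings, 2 other filters, DESeq2 1.42.0, limma 3.58.1 (voom with sample weights), non-robust estimation, 1 surrogate variable from sva 3.50.0, the RPKM table with pseudocounts of 1 and 0.1 (genes with RPKM of at least 1 in 5 or more libraries), thresholds of 0.10 and 0.01, and the omission of each library. The 5 further settings (own-total RPKM, thinned counts, a length correction, and 2 pairs of libraries left out) were chosen after seeing the data. The procedure was tested on simulated data drawn from the means, library sizes and dispersions of the 19325 genes, with 200 changed genes. For the comparison of exercise with control, edgeR recovered 6% of 50 genes changed 1.25-fold, 58% of 50 changed 1.5-fold, 78% of 50 changed 2-fold and 98% of 50 changed 4-fold, with 7 calls among unchanged genes. DESeq2 recovered 26%, 78%, 92% and 100%, with 37 such calls. The changed genes were picked among those with a mean of at least 1 CPM. Each gene was drawn independently, with no structure shared among libraries, so these calls do not measure the error rate in the real libraries. Figures were drawn with matplotlib 3.10.9.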

Results

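Brain transcriptomes were obtained from male killifish of 10 weeks and of 1 transgenic line, in 5 libraries labelled with swim-tunnel exercise and 5 without. Between 21.2 M and 38.1 M counts (M, 1000000) were assigned to genes per library. The exercise libraries held 29.5 ± 4.95 M counts (SD, n = 5) and the control libraries 24.8 ± 2.88 M (SD, n = 5), a difference that did not pass a two-sided exact permutation test (p = 0.103, adjusted p = 0.232 over 9 measures). The difference of 4.67 M was 2.52 M without exercise replicate 2. Of 26739 annotated genes, 22897 had at least 1 read and 19325 had enough counts to be tested. The 10 most counted genes took 3.68% ± 0.151 of counts in exercise libraries and 3.63% ± 0.0904 in control libraries (SD, n = 5 each), so that no few genes dominated any library. Pairs of libraries differed by far more than counting noise, with a chi-square per degree of freedom between 11.1 and 42.6 over the 45 pairs, so that no pair was 1 library listed again, though separately prepared libraries of 1 fish would also differ in this way.

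The comparison asked which genes of the brain differ in expression between fish with and without physical exercise. Exercise was accompanied by lower expression of 21 genes and higher expression of 12, out of 19325 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The changes were small for most of these 33 genes. Of the genes that fell, 5 fell by 2-fold or more, 6 by 1.5-fold to 2-fold and 10 by less than 1.5-fold. Of the genes that rose, none reached 2-fold, 3 rose by 1.5-fold to 2-fold and 9 by less than 1.5-fold. The median change was 1.69-fold among the genes that fell and 1.36-fold among those that rose. The changed genes were well expressed, with mean levels between 3.11 and 725 CPM and a median of 45.0 CPM, against a median of 17.1 CPM for all tested genes. Their median recovered length was 2985 bp, against 2685 bp for all tested genes.

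The gene that fell furthest was Nfu_g_1_021184 (recovered length 5443 bp), which stood at 134 ± 18.0 CPM in control brains and 27.2 ± 7.43 CPM in exercise brains (SD, n = 5 each). This was a 4.91-fold lower level (95% interval 3.72 to 6.50), with a log2 fold change of -2.30 ± 0.17 (SE) and an adjusted p of 0.000527 in edgeR's quasi-likelihood test. Raw counts of this gene lay between 519 and 1105 in exercise libraries and between 2430 and 4330 in control libraries. The next was Nfu_g_1_003740 (5993 bp), which fell 3.13-fold (95% interval 2.15 to 4.54), from 39.9 ± 8.48 to 12.8 ± 4.24 CPM (SD, n = 5 each; edgeR adjusted p = 0.0276). The largest rise was that of Nfu_g_1_023527 (4194 bp), from 30.3 ± 3.36 CPM in control brains to 59.7 ± 4.59 CPM in exercise brains (SD, n = 5 each). It was 1.97-fold higher (95% interval 1.73 to 2.26; edgeR adjusted p = 0.000527). Nfu_g_1_018930 (2985 bp) rose 1.75-fold (95% interval 1.43 to 2.13), from 33.4 ± 6.42 to 58.3 ± 5.67 CPM (SD, n = 5 each; edgeR adjusted p = 0.0381). In edgeR the call of Nfu_g_1_003740 was lost without any 1 of exercise replicates 1 to 4 or control replicates 1 to 4 (adjusted p 0.0606 to 0.0960). That of Nfu_g_1_018930 was lost in 11 of 26 alternatives, among them 1 surrogate variable (edgeR adjusted p = 0.0871) and the omission of any 1 of exercise replicates 1 to 4 or control replicates 1 to 3 (0.0658 to 0.118), whereas the other 2 genes passed in all 26. For each of these 4 genes every exercise library lay on one side of every control library. The files do not pair these identifiers with gene names.

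**Figure D1:**
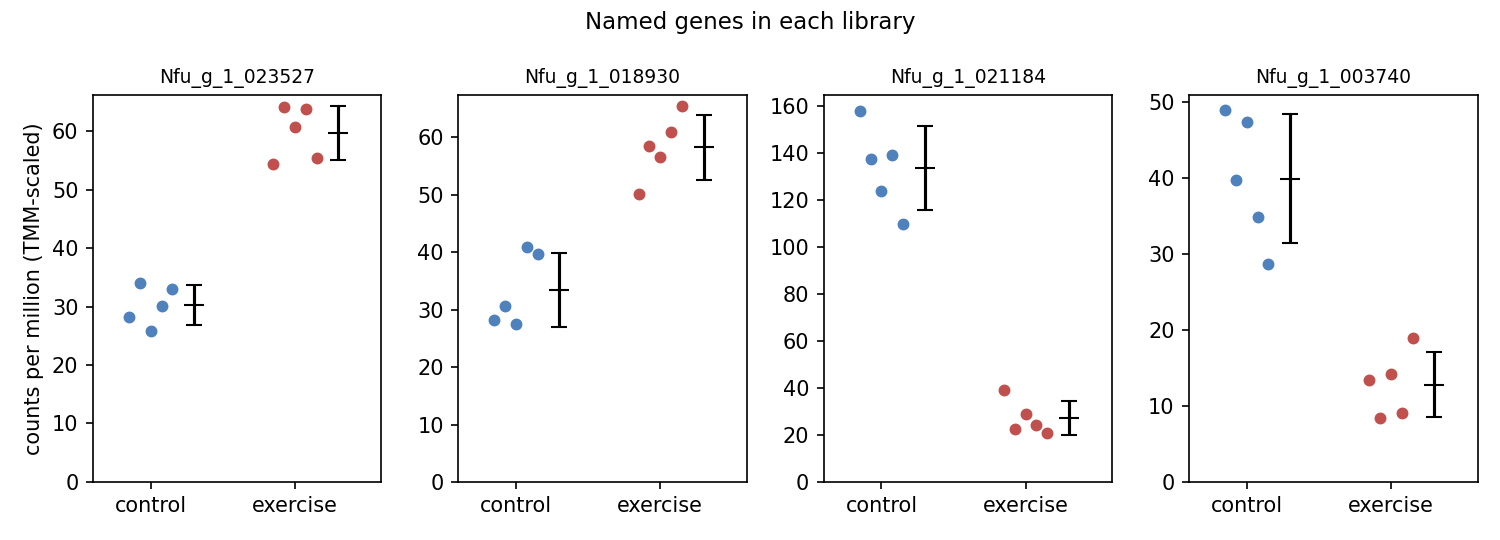
Expression of the 4 named genes in each library, in TMM-scaled CPM on axes that start at 0. Points are libraries (5 control in blue, 5 exercise in red) in replicate order, and black marks give the group mean ± SD. Nfu_g_1_021184 lay between 20.7 and 39.3 in exercise libraries and between 110 and 158 in control libraries.

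The smallest adjusted p among all genes, 6.14e-05 in edgeR's test, belonged to a gene that fell 2.35-fold, from 211 ± 18.3 CPM in control brains to 89.8 ± 7.35 CPM in exercise brains (SD, n = 5 each). The most abundant changed gene fell 1.37-fold, from 838 ± 15.8 to 612 ± 28.3 CPM (edgeR adjusted p = 0.000788, n = 5 each). The most abundant gene that rose went from 318 ± 16.2 to 415 ± 18.9 CPM (edgeR adjusted p = 0.0127, n = 5 each). The smallest change past the threshold was a 1.15-fold fall from 171 ± 2.00 to 148 ± 3.12 CPM (edgeR adjusted p = 0.0477, n = 5 each).

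**Figure D2:**
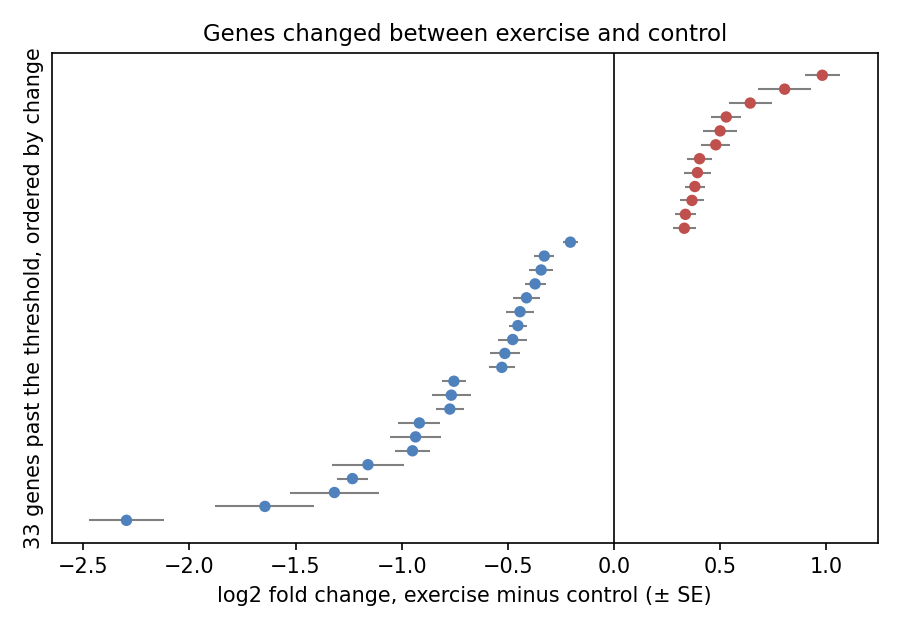
Log2 fold changes of exercise minus control for the 33 genes past the threshold, ordered by size, with horizontal bars of ± SE. The 21 genes that fell are in blue and the 12 that rose in red, and the values run from -2.30 to 0.98.

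In all 33 changed genes the 5 exercise libraries did not overlap the 5 control libraries. Over all tested genes this held for 524 (2.71%), where 0.794% or 153 genes would be so by chance. An unadjusted p under 0.05 in the edgeR test was found for 2264 genes (966 higher, 1298 lower), against 966 expected with no difference. Both expected numbers are averages, and genes vary together across libraries, so a single assignment of libraries to groups can lie far from them. Another assignment gave 737 edgeR calls. Neither count was taken for other assignments, so neither excess excludes chance. DESeq2 placed 388 genes past the same adjusted threshold, 163 higher and 225 lower, including all 33. With exercise replicates 1 to 5 left out in turn edgeR called 13, 11, 11, 14 and 91 genes, and with control replicates 1 to 5 left out in turn 17, 18, 18, 21 and 31. At the 91 genes called without exercise replicate 5, this library lay nearer to the other exercise libraries in 44 and nearer to the control libraries in 47. Each of the other libraries lay nearer to its own group at a share of 0.742 to 1 of the 11 to 31 genes called without it.

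Exercise was not the largest source of difference between the libraries. The first principal component (25.4% of variance) did not separate the groups, with mean scores of -7.12 ± 29.7 for exercise and 7.12 ± 22.1 for control (SD, n = 5 each; exact permutation p = 0.413, adjusted p = 0.595). Their difference, -14.2, was -9.22, -6.85 and -26.0 without exercise replicates 2, 4 and 5, and -8.67 without control replicate 3. Exercise replicate 5 had the highest score, 39.8, and the other exercise libraries lay between -36.7 and -1.12. The second component (18.0% of variance) was higher in exercise libraries, at 15.7 ± 12.2 against -15.7 ± 17.2 (SD, n = 5 each), which did not pass after adjustment (exact permutation p = 0.0238, adjusted p = 0.179). A single measure that separated the groups fully would reach an adjusted p of 0.0714 in this family of exact permutation tests, so missing the threshold carries little information. The median correlation of log2 CPM was 0.981 within exercise libraries, 0.980 within control libraries and 0.977 between the groups.

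**Figure D3:**
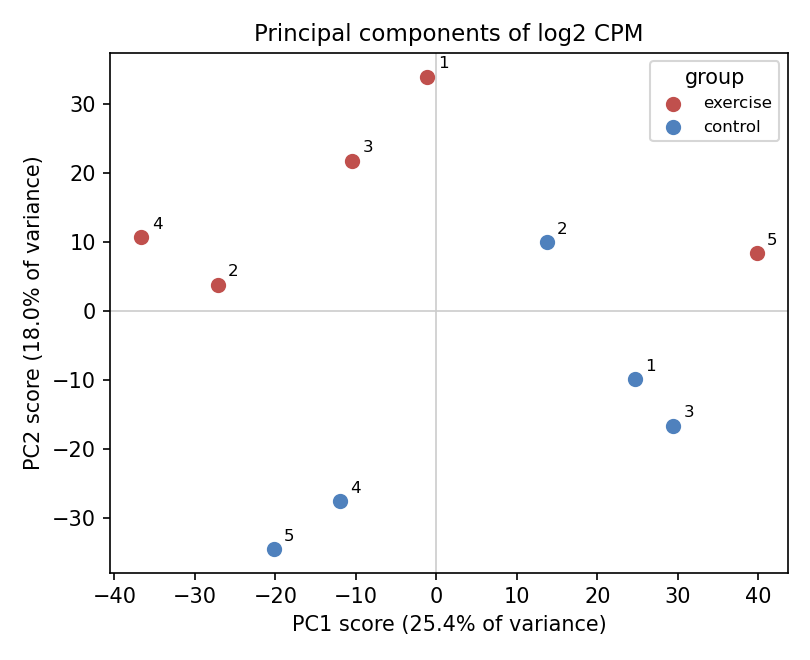
Scores of the 10 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis. Exercise libraries are red and control libraries blue, and numbers are replicates. Exercise replicate 5 lies at 39.8 on the first component, beyond the highest control library at 29.4.

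More genes were detected in exercise libraries, 21853 ± 103 against 21752 ± 57.9 (SD, n = 5 each; exact permutation p = 0.0794, adjusted p = 0.232), a difference of 102 that did not pass and was 63.5 without exercise replicate 2. The slope of log2 CPM on log2 gene length, relative to the mean library, was 0.00555 ± 0.00751 in exercise and -0.00555 ± 0.00561 in control libraries (SD, n = 5 each; exact permutation p = 0.0397, adjusted p = 0.179).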

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

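The thinning of counts, the removal of the length trend, the tests of exercise replicate 5 and the correlation with gene length were chosen after seeing the data, with their bounds written before their values were known, except that the joint omission of exercise replicate 5 and a control, and the correlation, were added after the other values had been seen.

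Exercise replicate 2 was far deeper than the other exercise libraries, at 38.1 M counts (M, 1000000) against 28.8 M for the next. This was the only one of 26 sets of 5 values in which a single library stood beyond Dixon's 95% limit, which chance exceeds in about 1 of 20. Unequal depth was not needed for most of the 33 calls: after all libraries were thinned to the smallest total, 30 of these genes were again past the threshold. Their median log2 change in the called direction was 1.001 times its former size. Thinning leaves the expected ratio of CPM unchanged, so this value could hardly have moved and decides nothing. Removing a smooth length trend left 1.007 times the size and again 30 of the genes past the threshold. The mean length slopes of the groups differed by only 0.0111 log2 CPM per doubling of length, so this size could hardly have moved either. The values show only that the trend removed does not account for most of the calls, and other forms of length bias were not tested. Differences in tank, day or handling between the groups are not given in the labels and cannot be told apart from exercise.

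Among 100 of the 126 splits of the libraries into 5 and 5, 3 (the real one included) gave 33 or more genes, and 70 of the other splits gave 0. Another split, exercise replicates 1, 3, 4 and 5 and control replicate 2 against the rest, gave 29 genes. Those 5 libraries are the second set under Other observations. Counted by direction, 4 of the 100 splits gave as many genes one way as the 12 higher, and 4 as many as the 21 lower, with 717 the most in another split. These shares lay under the bound set beforehand, but only narrowly, and part of the 126 splits was not run. Chance is therefore not excluded for the edgeR counts. The highest other count, 737, came from the split that parts the 5 libraries of highest score on the first principal component (exercise 1 and 5, control 1, 2 and 3) from the rest. This is many times the real count and points to a structure among the libraries that crosses the groups. DESeq2 was run on 31 of these splits, of which 3 gave 388 or more genes, with 1234 the highest, so chance was not excluded for that count. On the same 31 splits edgeR also reached its real count in 3, so the share was the same for both tools. The tools differed in their calls: over the other splits each was run on, the median was 10.5 genes for DESeq2 and 0 for edgeR.

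Exercise replicate 5 lay at the end of its group on the first component, though within Dixon's limit there (gap over range 0.535, limit 0.71) and on the other measures, and its omission raised the count of changed genes from 33 to 91, of which 32 were among the 33. Removing a smooth length trend left the score of this library at 39.7 (39.8 before) and its share of the component at 1.002 times its size, so the trend removed does not set this score. The removal did not flatten the slope of this library, which went from -0.00357 to 0.0069. The first component also follows the length slope (values below), so gene length bias is not excluded. A mislabelled sample met the bound written before the value was known, that it lie nearer to control at more than 0.5 of those 91 genes, but narrowly. Exercise replicate 5 was nearer to the other exercise libraries in a share of 0.4835 (44 genes). The exact 95% interval of 37.7% to 59.1% treats genes of 1 library as independent, so it is too narrow and does not measure doubt about the label. With 1 control also left out, exercise replicate 5 was nearer to exercise more often than that control in 4 of 5 fits, the exception being control replicate 1. An exchange with control replicate 1 had mixed support. Exchanging them gave 168 genes. Of 151 genes called with both left out, both libraries lay on the side of the other group at 61 and on their own side at 40. At 11 genes only exercise replicate 5 lay on its own side, and at 39 only control replicate 1 did. Nfu_g_1_021184 and Nfu_g_1_023527, past the threshold also without both, stood at 20.7 and 55.5 CPM in exercise replicate 5 and at 158 and 28.3 CPM in control replicate 1, as labelled. These genes had been picked from the fit with both libraries under their labels, where all 33 genes parted the groups fully. Their levels therefore do not weigh against an exchange. A wrong label, an exchange and a weaker response of the brain of exercise replicate 5, which was not tested, all stay open.

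Over the 10 libraries, the first component fell as the length slope rose (Pearson r = -0.799, permutation p = 0.00568; Spearman rho = -0.721, p = 0.0249; 1 relation computed). Without the 2 libraries farthest from the median slope r was -0.609. Recomputed after removal of the length trend, the first component had an r of -0.798 with the slopes of the uncorrected libraries.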

How the results depend on the processing

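All 33 changed genes kept their direction in every count-based alternative, and 31 did in the deposited RPKM table. The count stayed within 1.5 times of 33 under the 3 other scalings (31 to 36 genes), both other filters (31 and 39), non-robust estimation (33), 1 surrogate variable (23, of which 18 were among the 33) and, chosen after seeing the data, thinning (34), length correction (35) and RPKM rescaled to own totals (32). DESeq2 gave 388 genes (163 higher, 225 lower) and voom with sample weights 99 (32 higher, 67 lower), each including all 33. The cause was not tested. At an adjusted p below 0.10 there were 106 (39 higher, 67 lower), and below 0.01 there were 10 (1 higher, 9 lower). The RPKM table as deposited turned the balance of directions, with 31 higher and 6 lower (pseudocount 1) or 30 higher and 6 lower (pseudocount 0.1), a median shift of all genes by 0.208 and 0.245, and 9 of the 33 genes past the threshold. Its library totals were misplaced, and with own totals the split was 10 higher and 22 lower. Without exercise replicates 1 to 5 in turn, 13, 11, 11, 14 and 91 genes were called, and without control replicates 1 to 5 in turn 17, 18, 18, 21 and 31. The ranges were 11 to 91 in all, 1 to 27 higher and 9 to 64 lower. With exercise replicate 5 and control replicate 5, the libraries of lowest voom weight (0.433 and 0.640), both left out, 82 genes were called (26 higher, 56 lower). With exercise replicate 5 and control replicate 1 left out, 151 were called (29 higher, 122 lower), 28 of them among the 33. Both pairs were chosen after seeing the data, which favours larger counts. Nfu_g_1_021184 (log2 fold change -2.47 to -1.66, adjusted p at most 0.00375) and Nfu_g_1_023527 (0.90 to 1.34, at most 0.00394) were past the threshold in all 26 alternatives. Nfu_g_1_003740 (-1.93 to -1.02, adjusted p up to 0.0960) missed it in 8, each of which left out 1 library. Nfu_g_1_018930 (0.70 to 0.89, adjusted p up to 0.118) missed it in 11. Their direction never turned. None of the 9 measures per library passed in the 11 alternatives, which says little, since alone at the smallest exact p one would reach an adjusted p of 0.0714. No paired analysis was possible because the groups share no numbers in the labels. The gene list tests were not run. Thinning did not lower the count. It went only to 21.2 M counts, from means of 29.5 M in exercise and 24.8 M in control libraries. Such a cut could hardly show whether depth limits the calls, so this stays open.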

Other observations

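All tests of this part were chosen after seeing the data, and the definition of the genes below was itself revised once after a first look at such genes. A group of genes stood at a high level in some libraries (on) and a much lower level in the others (off), in sets of libraries other than the exercise and control groups. Sorting the libraries by log2(CPM + 0.5) and requiring a gap of at least 4-fold between neighbouring libraries, 50 genes with a maximum of at least 2 CPM split the 10 libraries with 2 to 8 on the high side, and none of these splits matched the groups exactly. Association of the sets with exercise was not tested. Of these genes, 13 were on in exactly the same 4 libraries (exercise replicates 2 and 4, control replicates 1 and 4), and 10 in another 5 (exercise replicates 1, 3, 4 and 5, control replicate 2), a set that holds 4 of the 5 exercise libraries and 1 of the 5 control libraries. The most abundant was Nfu_g_1_014206, chosen after its values were seen, with 24480 to 46580 counts in the 5 libraries of the second set and 9 to 379 in the others. In the first set, Nfu_g_1_006592 had 1320 to 2076 counts where on and 71 to 135 where off. None of the 50 genes was among the 33 changed with exercise. This says little, since all 33 parted the groups fully and none of the 50 had its largest gap between the groups.

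Shared sets of this size are not expected by chance: shuffling the on libraries of each gene 10000 times gave at most 4 genes with one set (permutation p = 1e-04, the smallest these shuffles can give). Reads moving to a near-identical copy could leave genes with the opposite pattern, and the share of the 23 genes with such a partner was 0. A partner counted only if it split by at least 4-fold itself, with exactly the opposite set. A copy with a steady level of its own could gain reads without such a gap, so this explanation is not excluded. Tissue carried over in some libraries also stays open. It would bring genes at graded levels, and 13 genes followed these sets by less than 4-fold beside the 23 that were on or off, a ratio of 0.565 between the bounds set for and against it. A candidate explanation is a pair of inherited haplotypes that segregate in this line and carry alleles that are not expressed or not aligned, which could be tested by calling variants in the reads. This hypothesis was not tested. Of the 50 genes, 2 pairs lay in adjacent rows of the table, against a mean of 0.0903 in 10000 shuffles (permutation p = 0.0041). The shuffles drew from all 26739 rows, 3842 of them without a read, so this p is too small. A pair did not need to share a set. Genes of the first set were spread over rows 1523 to 23184, and those of the second over rows 130 to 22811. Whether rows follow the genome is not given in the sources used here, and a gene annotated in parts would also give adjacent pairs.

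Fold changes of genes in neighbouring rows of the table were correlated across 15210 adjacent pairs of tested genes (Spearman rho = 0.110 across genes, which are not independent replicates). Over the other 125 splits of the libraries rho lay between 0.0484 and 0.109.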
